A study of Drosophila melanogaster with 3 samples.

How the data were processed

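The data are chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an anti-GFP antibody, from 3 biological replicates of transgenic embryos collected over 0 to 24 hours. Per the labels, chromatin was fragmented by sonication. A control experiment that the labels name as possible was not analysed here.

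The authors deposited peak lists on the dm6 assembly, per the deposited records. Each sample had a ranked list and an IDR-thresholded list made from its own reads, and the series had 4 further pairs made from the reads of all 3 samples, 1 of them called conservative. Which pooling each of the other 3 pairs stands for, and the aligner, the peak caller and their versions, are not given in the sources used here. The signal value of each peak is the authors', its scaling is not stated, and it served only to describe, rank or filter peaks within 1 list. The −log10 of the global IDR in each ranked list is also as deposited by the authors. Another column gives the summit offset within each peak, as deposited. Read depth is unknown, so intervals cover the counting of peaks or genes only, and a site missing from a list is not shown to be unbound.

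Lists of a replicate were paired by sample. Each series-level thresholded list was paired with the only series-level ranked list in which all of its peaks had a −log10 IDR of at least 2. The same bound held in the replicates. The thresholded lists therefore hold peaks with an IDR of 0.01 or less, and the stricter setting planned at 0.01 moved nothing. Ranked peaks above that IDR are called failed candidates, 144232 of them for the conservative list. A further 121 peaks were at or under the threshold yet missing from the conservative list, and they were kept out of both sets. The thresholded lists of any 2 replicates shared 0 identical entries.

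Sequence was taken from the Release 6 assembly, and genes from the Ensembl 115 annotation (BDGP6.54) without pseudogenes and transposable elements. Summits were classed in the order promoter (within 500 bp of a TSS), 5' UTR, 3' UTR, coding exon, non-coding exon, intron, intergenic. Non-coding exons were those of non-coding genes, and exon sequence of coding genes that is neither UTR nor coding. Peaks off the assembled chromosomes had no class or distance. Classes, chromosome arms and gene lists were tested with two-sided Fisher's exact tests and odds ratios with 95% intervals by the log method, the distance to the nearest TSS with a two-sided permutation test of the difference of median log10 distance, with 100000 permutations. Shares carry exact (Clopper-Pearson) 95% intervals. The 21 gene lists and 24 motif consensus sequences were fixed before the data were examined. A gene counted as having a peak when a summit lay within 1 kb of any of its TSSs. List members were compared with other protein-coding genes that had a candidate in that window, and the tRNA, snoRNA and snRNA lists with all other genes. Neighbouring genes can share a peak, so genes in these tests are not fully independent.

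Motifs were searched on both strands within 100 bp of the summit. They were compared with windows 500 bp to either side by the exact McNemar test, keeping the weaker p, and with failed candidates by Fisher's exact test. A motif was called only where both adjusted p were under 0.05 in 1 direction. All 8-mers were ranked on X, 2L and 2R and the best 10 tested on 3L, 3R and 4. P-values were adjusted by the Benjamini-Hochberg method within each family. Peaks are not independent biological replicates, and p-values treat each as 1 observation. The comparison for the overlap of replicates came from 1000 draws of failed candidates, which leave out a replicate's own passing peaks. Genes were named by a rule also set beforehand: those with the nearest TSS within 1 kb of the 25 peaks of highest signal called in all 3 replicates, CG2889, and up to 4 members of each list with the highest signal. Other names given, such as further list members and the genes near the remaining top peaks, were chosen after their values were seen.

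The alternatives were another peak list, a stricter IDR, peaks called in both remaining replicates after leaving out each in turn, other overlap rules, 10000 random positions as background, other promoter, gene and motif windows, all annotated genes, promoter peaks alone, and exchanged arms. Leaving out a replicate filters the conservative list, which was itself made from all 3. Added after seeing the data were an IDR of 0.001 or less, the left-out peaks counted as passing, the peaks' flanks for the 8-mers, and 3L, 3R and 4 alone for CACTGTG in left-out peaks.

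The tests were tried on simulated data. With a planted promoter odds ratio of 6, the median of 20 draws of 2208 peaks was 6.11, and 18 of 20 intervals held the planted value. With nothing planted, any class was called in 2 of 20 draws, any arm in 0 of 20, the distance in 1 of 20 and any gene list in 1 of 100. With the share of genes with a peak raised to about that observed, a ribosomal protein list of 79 genes was called in 100 of 100 draws and an insulator list of 16 genes in 49, so lists of that size can be missed. Planted 8-mers were recovered in 10 of 10 draws, and a motif planted in 3% of windows in 20 of 20, by the flank test alone. Motifs as rare as Motif 1 (1.15% of summits) were not tried, nor was the rule that needs both tests. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.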

Results

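Peaks for CG2889 were mapped in whole Drosophila melanogaster embryos aged 0 to 24 hours. The embryos carried a CG2889-eGFP fusion, and chromatin was immunoprecipitated with an antibody against GFP. A control experiment was not analysed here, so peaks that do not come from the fusion cannot be told apart. To general knowledge CG2889 encodes a C2H2 zinc finger protein of the ZAD family, a large insect family of DNA-binding proteins. The series holds 1 group of 3 biological replicates and no second condition, so the comparisons made here are between replicates and between called peaks and candidates that failed the threshold. Each replicate came with a ranked list of candidate peaks and a shorter list filtered by the irreproducible discovery rate (IDR). Read depth is unknown, since the lists hold no read counts. The thresholded lists held 1567 peaks in replicate 1, 1190 in replicate 2 and 1300 in replicate 3, a mean of 1352.3 ± 193.9 (SD, n = 3). The candidate lists behind them held 111523, 116237 and 111388 peaks. The conservative list of the whole series held 2208 peaks with a median width of 330 bp, and is the list used below unless another is named. Its peak widths summed to 0.682 Mb, with sequence in overlapping peaks counted more than once. Coordinates are those of dm6.

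The question of how well the replicates match was answered by overlap. The strongest sites were shared by the replicates far more often than the weaker ones. Of the 500 peaks of highest signal in replicate 1, 93.2% overlapped a thresholded peak of replicate 2 and 96% one of replicate 3. Over whole lists, 60.8% of replicate 1 peaks lay in replicate 2 (exact 95% interval 58.3 to 63.2%) and 64.8% in replicate 3 (62.4 to 67.1%). Replicate 2 had 79.7% of its peaks in replicate 1 and 73.2% in replicate 3. Replicate 3 had 78.1% in replicate 1 and 67% in replicate 2. The mean over the 3 pairs was 70.6 ± 0.729% (SD between pairs, after both directions of each pair were averaged). That SD leaves out the spread of the single comparisons, from 60.8 to 79.7%. Failed candidates of the same replicate, drawn in the same number, overlapped at 0.229 to 0.542% on average and never above 1.34% in 1000 draws per comparison. These draws leave out the replicate's own passing peaks. Their low share thus follows in part from the overlap itself and is not a chance level of agreement.

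**Figure D1:**
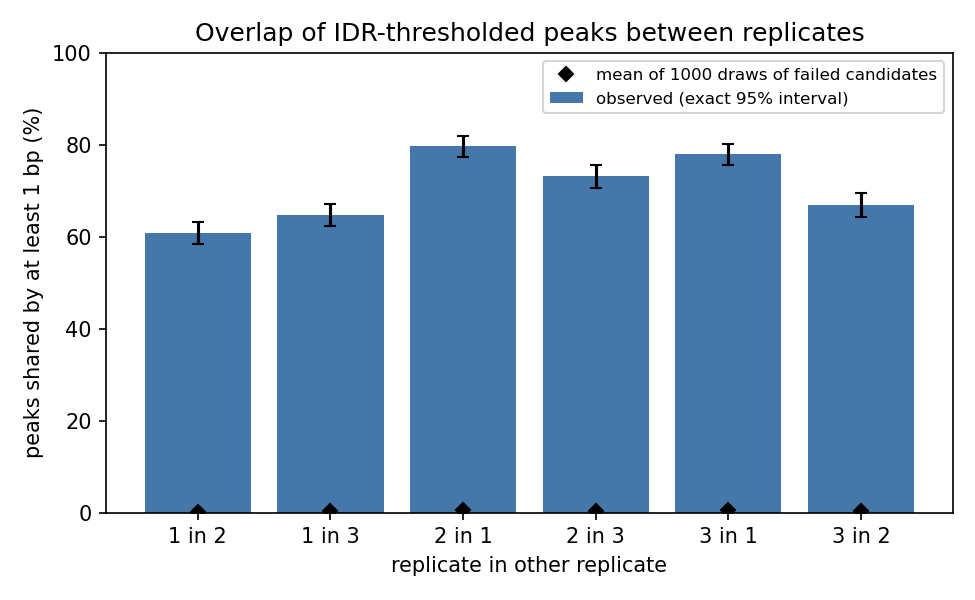
Percent of each replicate's thresholded peaks (vertical axis) that overlap a thresholded peak of another replicate by at least 1 bp, for the 6 ordered comparisons (horizontal axis). Bars carry exact 95% binomial intervals and diamonds give the mean of 1000 draws of failed candidates. The bars lie between 60.8 and 79.7%, and the diamonds do not exceed 0.542%.

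Of the 2208 conservative peaks, 812 (36.8%, exact 95% interval 34.8 to 38.8%) overlapped a thresholded peak in all 3 replicates. Another 422 did so in 2 replicates, 482 in 1 and 492 (22.3%) in none. The median deposited signal value was 226 for peaks found in all 3 replicates and 82.6 for those found in none. The other 3 lists of the whole series, of 3145, 2050 and 1934 peaks, held 91.1, 75.6 and 75.1% of the conservative peaks with the same start and end.

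For 20 of the 25 peaks of highest signal called in all 3 replicates, the nearest protein-coding transcription start site (TSS) was within 1 kb, at a median distance of 112 bp. The first was the peak at 3L 19590480 to 19590747, 91 bp from the TSS of CG14100, with a signal of 1781. The next was at X 2703737 to 2704023, 42 bp from the TSS of Ugalt, a UDP-galactose transporter gene, with a signal of 1686. Named peaks also lay at mRpL41 (2R 15217611 to 15217890, signal 1554) and mRpL23 (3L 2373481 to 2373740, signal 956) of the mitochondrial ribosome, the polynucleotide phosphorylase gene PNPase (signal 1048), and eIF6, a factor of the large ribosomal subunit (signal 1063). Others lay at ph-p of the Polycomb group (X 2137223 to 2137490, signal 1202), the chromodomain protein gene Chro (3L 22878762 to 22879028, signal 1093), the HMG-box gene HmgZ (signal 1211, in an intron, 558 bp from the TSS) and the transcription factor gene Adf1 (signal 989, in an intron, 762 bp from the TSS). The others were CG8320, Tcs5, CG5611, CenG1A, Art3, Atat, CG7601, px, GstE13 and Fkbp14, with signals from 861 to 1370. None of the 20 ranked lower than 31 by signal in any replicate's own thresholded list. The remaining 5 peaks had their nearest protein-coding TSS farther off, between 1024 bp (CG11050, peak in an intron) and 11919 bp (CG13323, intergenic).

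At its own gene, CG2889 had a weak peak. The transgene can change the copy number of this locus, and its part in the signal was not tested. The peak alone therefore does not show binding there. The gene lies at X 10473938 to 10477201 on the forward strand, and the conservative list held 1 peak within 5 kb of it, at X 10474682 to 10475011, whose summit is 131 bp from a TSS of the gene. Its signal was 85.6 and its rank 2227 among 146561 candidates. Replicate 1 called a peak there (X 10474728 to 10475003, signal 41.2, rank 1536). Replicates 2 and 3 called none in the region, and their best candidates there ranked 3013 and 3135. The same interval passed in the series-level lists of 1934 and 2050 peaks (IDR 0.00972 and 0.00552). In the longest it did not, with an IDR of 0.535, and 1 other peak within 5 kb of the gene did.

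Promoters held the largest share of sites. Summits within 500 bp of a TSS made up 1101 of the 2172 conservative peaks on the assembled chromosomes (50.7%, exact 95% interval 48.6 to 52.8%), against 14.3% of the 141543 candidates that failed the threshold (odds ratio 6.16, 95% interval 5.65 to 6.7). Among peaks called in both remaining replicates when 1 was left out, the odds ratio was 9.03 to 9.82. The classes are exclusive and promoters come first, so their higher share lowers the shares left to the other classes. Odds ratios under 1 in those classes follow in part from this. Introns held 33.9% of peaks and 36.6% of failed candidates (odds ratio 0.89, Fisher adjusted p = 0.013). In counts, introns and intergenic sequence held 737 and 255 peaks, against 51783 and 33792 failed candidates. Shares among summits outside promoters were not tested. Coding exons held 1.75% against 20.1% (odds ratio 0.071), 3' UTRs 0.645% against 3.42% (odds ratio 0.183), 5' UTRs 0.414% against 0.962% (odds ratio 0.429, Fisher adjusted p = 0.00988) and intergenic sequence 11.7% against 23.9% (odds ratio 0.424). Non-coding exons did not pass the threshold (0.829% against 0.793%, Fisher adjusted p = 0.807). The median distance to the nearest TSS was 480 bp for peaks and 2823 bp for failed candidates, a difference of -0.77 in log10 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The intron result turned with the promoter definition: within 200 bp of a TSS its odds ratio was 1.11 (Fisher adjusted p = 0.0203). The 5' UTR result was lost without any 1 of the 3 replicates, with odds ratios of 0.447 to 0.504, at an IDR of 0.001 or less, a setting chosen after seeing the data (0.423, Fisher adjusted p = 0.111), and with a promoter of 200 bp, at 0.73 (Fisher adjusted p = 0.136).

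**Figure D2:**
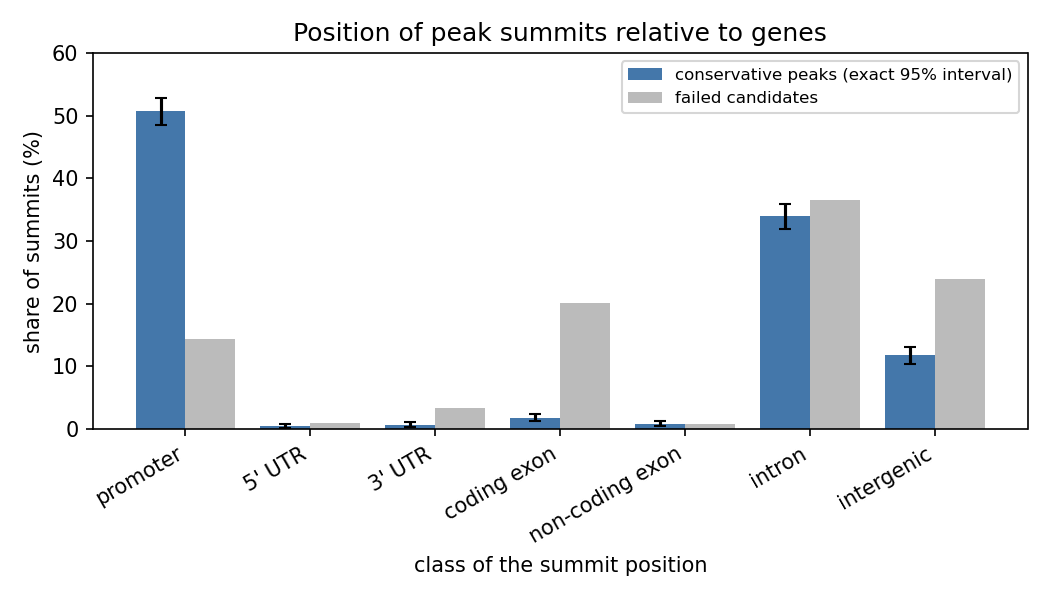
Share of summits (vertical axis, percent) in each class of position relative to genes (horizontal axis), for conservative peaks with exact 95% intervals and for candidates that failed the IDR threshold. Promoters hold 50.7% of peaks and 14.3% of failed candidates, and coding exons 1.75 and 20.1%.

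Peaks lay on all the large chromosome arms, at 14.6 to 18.6 per Mb. Arm X held 439 peaks, 18.6 per Mb (exact Poisson 95% interval 16.9 to 20.5), and 3R held 467, 14.6 per Mb (13.3 to 15.9). Against failed candidates X was higher (odds ratio 1.16, adjusted p = 0.022) and 3R lower (odds ratio 0.813, adjusted p = 0.000498) by Fisher's exact test. The Y chromosome had 0 peaks and 651 failed candidates (Fisher adjusted p = 0.000498), a call lost at an IDR of 0.001 or less (adjusted p = 0.0531) and without any 1 replicate (adjusted p 0.0501 to 0.134). Arms 2L (409 peaks), 2R (389), 3L (465) and 4 (3), and the 36 peaks on other contigs, did not pass the threshold, though 2L did at an IDR of 0.001 or less (odds ratio 1.26, Fisher adjusted p = 0.0185) and 3L in the longest list (1.11, adjusted p = 0.0479). Arm 4 was lower against random positions (odds ratio 0.141, Fisher adjusted p = 7.41e-05), and the other contigs were higher with left-out peaks counted (1.66, adjusted p = 0.000442). The X result was lost in the longest series-level list (odds ratio 0.987), at an IDR of 0.001 or less (1.2, Fisher adjusted p = 0.0531) and without any 1 replicate (odds ratios 1.15 to 1.17, adjusted p 0.0725 to 0.2), and 3R was past the threshold only without replicate 2 among those 3 settings. Without replicates 1 or 3 no arm passed.

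A total of 1848 genes, 1637 of them protein-coding, had a summit within 1 kb of a TSS. Of the gene groups, genes for cytoplasmic ribosomal proteins had the largest excess in the conservative list with this window. A summit lay within 1 kb of a TSS for 32 of 81 of them (39.5%, exact 95% interval 28.8 to 51%), against 12.7% of the other protein-coding genes with a candidate (odds ratio 4.48, 95% interval 2.86 to 7.02, adjusted p = 3.25e-08). RpS27 (signal 341), RpL34b (271), RpL32 (245) and RpL7 (231) had the strongest of these peaks, and 9 of the 32 genes had a peak called in all 3 replicates. Genes for insulator and architectural proteins, which organise chromatin domains, had peaks at 6 of 16 (37.5%, odds ratio 4.06, Fisher adjusted p = 0.0484): Chro (signal 1093), Cp190 (330), Trl (267) and pzg (181) were the strongest, with pita and M1BP. Neither list passed the threshold among peaks also called in the remaining replicates. Without replicates 1, 2 or 3 the ribosomal protein odds ratio was 2.02, 1.56 and 2.4 (Fisher adjusted p = 0.225, 0.687 and 0.0613), and at an IDR of 0.001 or less, it was 1.45 (adjusted p = 0.731). The insulator odds ratio stayed between 3.07 and 4.29 in these settings, with Fisher adjusted p between 0.128 and 0.372. In them it was above the ribosomal protein odds ratio, so the order of these lists turned. The insulator list did not pass with summits within 5 kb either (odds ratio 2.01, Fisher adjusted p = 0.288), within 200 bp (5.25, adjusted p = 0.0668), with left-out peaks counted (3.98, adjusted p = 0.0531) or with all annotated genes (3.49, adjusted p = 0.0632).

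Genes for odorant and gustatory receptors, cuticle proteins and tRNAs had fewer peaks than other genes. Of 157 odorant and gustatory receptor genes 1 had a peak, Gr68a (signal 92.1, odds ratio 0.0427, Fisher adjusted p = 1.32e-07), and of 84 cuticle protein genes 0 had one (adjusted p = 0.000143). tRNA genes had a peak nearby for 14 of 251 (5.58% against 11.6% of all other genes, odds ratio 0.452, Fisher adjusted p = 0.00979), the strongest being the one 831 bp from tRNA:Val-TAC-1-1 (signal 627).

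The other 16 lists did not pass the threshold. ZAD zinc finger genes, the family of CG2889, had peaks at 13 of 66 (19.7%, Fisher adjusted p = 0.26), led by CG1792 (signal 728), CG1602 (314), D19B (243) and CG4707 (241). The 13 include CG2889 itself, whose peak alone does not show binding, and D19A and CG7386, which share 1 peak. Polycomb and Trithorax group genes had peaks at 6 of 26 (Fisher adjusted p = 0.318), among them ph-p (signal 1202), brm (587), E(z) (246) and Su(z)12 (195). Heat shock genes had 4 of 13 (Fisher adjusted p = 0.227), with Hsp27 (signal 356), Hsp83 (183), Hsp26 (125) and Hsc70-4 (124). No Hox or segmentation gene of 24 had a peak (Fisher adjusted p = 0.224). Neural genes had 5 of 24, with elav (signal 376), brat (341) and numb (281). Genes of muscle and mesoderm had 3 of 23 (sls, tin and htl), of the cell cycle and replication 6 of 36, with Dp, dpa, Mcm2 and RnrS first, and of the piRNA pathway and germline 5 of 26, with armi, egl, piwi and bgcn first. Ecdysone genes had 3 of 21 (Eip75B, EcR and Hr78), and genes of Dpp, EGFR and Notch signalling 5 of 30, with spi, Mad, brk and E(spl)m3-HLH first. Proteasome genes had 4 of 43 (Rpn13, Rpn3, Rpn5 and Rpn6) and oxidative phosphorylation genes 9 of 81, with ND-ASHI, ND-24, ND-51 and ND-MWFE first. snoRNA genes had 28 of 233 and snRNA genes 3 of 25. Some of these lists passed in other windows: snoRNA genes were higher with summits within 5 kb (odds ratio 1.94, Fisher adjusted p = 5.65e-06) and lower within 200 bp (0.0783, adjusted p = 0.000893), and oxidative phosphorylation genes were higher within 5 kb (2.05, adjusted p = 0.00747). The list of chorion and vitelline membrane genes had 1 of 16, which was Cp190, an architectural protein gene that the name pattern of the list took in. Of 111 replication-dependent histone genes only 1 had a candidate in the window and could be tested, and it had no peak. With all annotated genes as background the list was lower (Fisher adjusted p = 1.22e-05). The lack of candidates at the other histone genes fixed that outcome, so it does not show that peaks avoid them. Adjusted p for these further lists lay between 0.474 and 1.

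**Figure D3:**
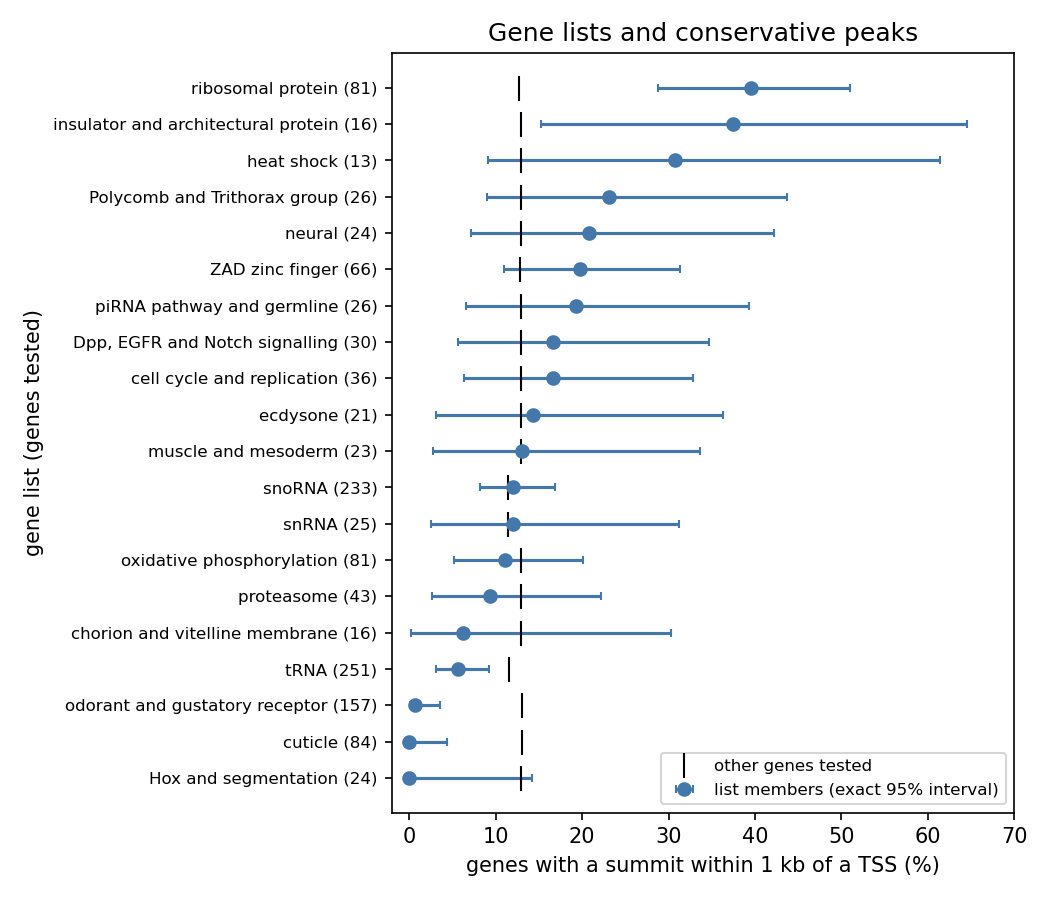
Percent of genes with a conservative summit within 1 kb of a TSS (horizontal axis) for the lists with at least 10 genes tested (vertical axis, number tested in brackets). Points carry exact 95% intervals and ticks mark the other genes tested. Ribosomal protein genes stand at 39.5% against 12.7%, and odorant and gustatory receptor genes at 0.637%.

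Several motifs, some of them core promoter elements, were more frequent at summits than in the same peaks' flanks and than in failed candidates. Neither background matched the base composition of the summit windows. On 3L, 3R and 4 these were 63.5% A and T, against 56.2% in flanks and 53.1% in failed candidates. The motifs were not searched in shuffled windows of the same composition, so base composition is not excluded as a source of the higher and lower calls. The DRE or BEAF-32 site TATCGATA, a boundary and housekeeping promoter element, was found within 100 bp of 2.44% of summits, against 0.645% of either flank and 0.373% of failed candidates (odds ratio 6.69, 95% interval 5.03 to 8.9). Motif 1, GGTCACACT, the site of M1BP, was found at 1.15% of summits against at most 0.46% of flanks (odds ratio 6.13). With peaks and failed candidates both limited to 500 bp around a TSS, the odds ratios of the DRE and Motif 1 were 3.46 and 2.87. Ohler motif 7 stood at 9.3% against at most 4.93% (odds ratio 1.93), and the TATA box at 4.19% against 2.44% (odds ratio 2.35). The homeodomain core TAATTA was at 17.5% against 11.6% (odds ratio 2.12), and WGATAA at 26.8% against 22.2% (odds ratio 1.9). The BEAF-32 core CGATA was at 25.9% against 22.3% (odds ratio 1.41). The pyrimidine TCT element was searched as YTYTTTYY, which runs of T alone also match. It stood at 35% against 30.9% (odds ratio 1.83). The median promoter summit lay at -116 bp from the nearest protein-coding TSS, so many windows of 100 bp either side ended short of it. The E-box CANCTG (28.6% of summits, odds ratio 0.639) and the Pho site (6.68%, odds ratio 0.615) were lower than in both backgrounds, with adjusted p of 0.0417 and 0.0467 against the flanks (exact McNemar test). The Pho call was lost in each other list, window and set of peaks tried, and the E-box call in the longest list (exact McNemar adjusted p = 0.432). GAGA repeats were above failed candidates (odds ratio 1.44) but below the flanks (3.73% against 5.25 and 5.43%), and the former was lost at an IDR of 0.001 or less (1.3, Fisher adjusted p = 0.272), without any 1 replicate (1.35 to 1.46, adjusted p 0.0658 to 0.162) and among promoter peaks (1.12, adjusted p = 0.558). The sites of Zelda, CTCF, su(Hw), Caudal, Hsf, E2F, ewg, Twist and Grainyhead, the CRE, the Initiator, the DPE and Ohler motif 6 did not pass in both tests. In the peaks also called in both remaining replicates, 2 to 4 motifs were higher against both backgrounds in place of 8. TAATTA and Ohler motif 7 were among them without each of the 3 replicates. The DRE was lost without replicate 3 (exact McNemar adjusted p = 0.1), and CGATA, Motif 1, TCT and WGATAA were never among them. The TATA box was lost without replicate 1 (exact McNemar adjusted p = 0.289) and without replicate 3 (0.157). WGATAA also lost the call in the longest list (exact McNemar adjusted p = 0.0881), and Motif 1 with left-out peaks counted (0.103). Against failed candidates CGATA (odds ratio 1.33 to 1.4), TCT (1.73 to 1.87) and WGATAA (1.8 at the lowest) still passed without each replicate, and only the comparison with the flanks was lost, in fewer peaks. In windows of 50 bp either side the DRE (odds ratio 4.42, exact McNemar adjusted p = 0.192), Ohler motif 7 (1.34, adjusted p = 0.148) and the TATA box (2.63, adjusted p = 0.0676) lost the call, as did CGATA and TCT. Motif 1 had an odds ratio of 3.04 without replicate 1 (Fisher adjusted p = 0.0545) and 2.06 in those windows (adjusted p = 0.205), and GAGA turned to 0.596 in the latter (adjusted p = 0.0596).

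An open search of 8-mers found 2 kinds of sequence. The 10 best ranked on X, 2L and 2R were all more frequent at summits than in failed candidates on 3L, 3R and 4, with odds ratios of 3.94 to 5.54 and Fisher adjusted p from 7.27e-38 to 1.72e-12. Of these, 7 held A and T alone, such as TTAAAAAA (11.8% of 935 summit windows against 2.53% of failed candidates) and ATATTTTA (11.4% against 2.41%). The other 3 shared CACTGT or its reverse complement: CACAGTGG (5.13% against 0.968%), CACTGTGC (4.81% against 0.946%) and ACAGTGGG (3.64% against 0.8%). The peaks' own flanks, compared after the data had been seen, held each of the 10 less often. With windows of 50 bp either side, or with discovery on 3L, 3R and 4, all 10 best ranked 8-mers were of A and T alone.

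**Figure D4:**
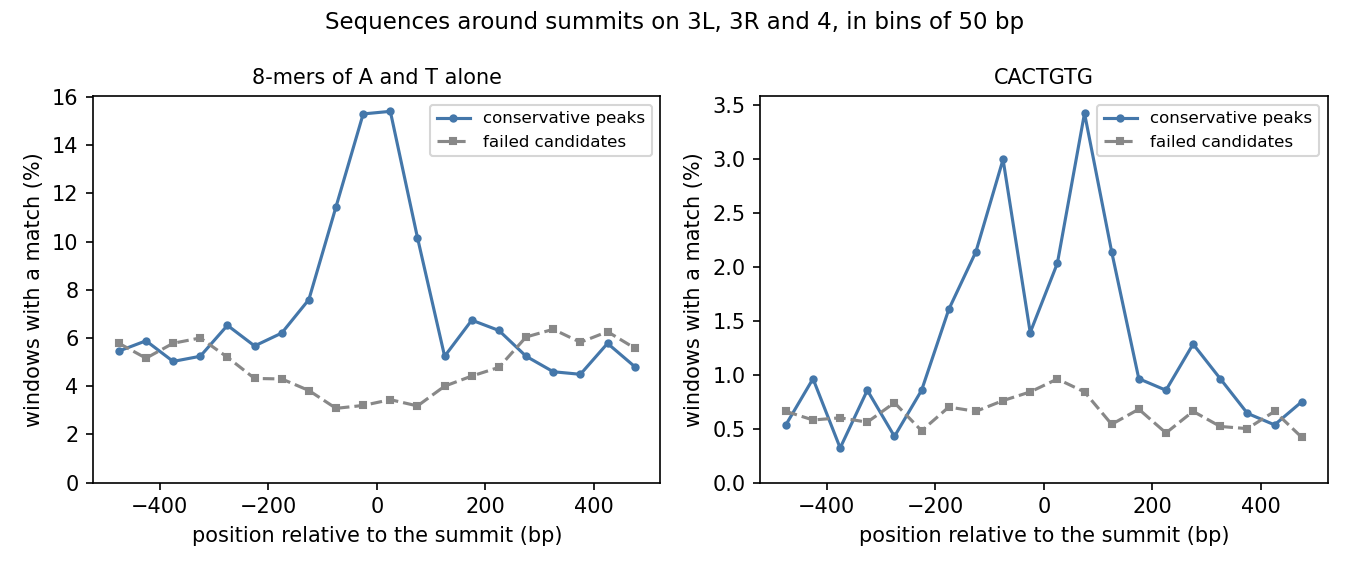
Percent of windows with a match (vertical axis) by position relative to the summit in bins of 50 bp (horizontal axis), on 3L, 3R and 4, for 935 conservative peaks and 5000 failed candidates drawn at random. The 7 8-mers of A and T alone reach 15.4% of peaks beside the summit. CACTGTG reaches 2.99% in the bin from -100 to -50 bp and 3.42% in the bin from 50 to 100 bp. It is lower in the bins next to the summit, at 1.39% before and 2.03% after it.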

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

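The tests of the 2 explanations of the ribosomal protein excess by transcription and by weaker peaks, and the comparison of left-out peaks on 3L, 3R and 4 alone and by promoter share, were chosen after the result was seen. All 3 patterns were noticed in these data. The design has 1 group and offers no biological explanation, so none was tested by comparing groups. The bounds for the flanks and for removed regions were set before their results and kept unchanged when the patterns were later cut to 3, after flank shares of single 8-mers and the overlap of left-out peaks had been printed. An exact McNemar condition was added to the flank test at that point.

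A total of 121 peaks were at or under the IDR threshold and yet missing from the conservative list, which drew attention as a signal in data that the comparisons leave out. Of these, 86 lay on the chromosome arms and 35 elsewhere, 45 had a signal above 128, the median of the kept peaks, and the strongest on the arms were near cbt (2L 480939 to 481235, signal 1603), Lk6 (3R 11760930 to 11761158, signal 979) and larp (3R 28326491 to 28326697, signal 700), named after their values were seen. Left-out peaks summed to 778 over all lists, which share reads, so 1 region can count in several lists. Of the 778, 1 (0.129%) overlapped a peak kept in any list, which would be seen if the authors had removed fixed genomic regions. Whether the left-out peaks are sites like the kept ones stays open. Of 86, 2 held CACTGTG against 217 of 2172 kept peaks (odds ratio 0.215, 95% interval 0.0524 to 0.878). However, the bound set for this overlooked that the sequence had been found in kept peaks on X, 2L and 2R. On 3L, 3R and 4 alone it was 2 of 46 against 79 of 935 (0.493, 0.117 to 2.07). Promoters held 25 of the 86 (29.1%) against 50.7% of kept peaks (odds ratio 0.399, 0.248 to 0.64), which makes them unlike the kept ones in position, but the promoter content of the removed regions was not tested.

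The excess of peaks at ribosomal protein genes was weighed against 3 explanations. Promoters shared with a gene whose TSS lies within 500 bp are argued against, since among genes without such a neighbour the odds ratio was 5.17 (95% interval 2.53 to 10.6). With summits counted within 1 kb, a peak can still be shared with a gene farther off, which was not tested. Strong transcription in general stays open: proteasome and oxidative phosphorylation genes had a pooled odds ratio of 0.79 (0.443 to 1.41), but oxidative phosphorylation genes were higher with summits within 5 kb (2.05, Fisher adjusted p = 0.00747), and expression was not measured here. Among genes with a peak, 8 of 32 ribosomal protein genes (25%) had one with an IDR of 0.001 or less, against 56.5% of others (odds ratio 0.257, 95% interval 0.115 to 0.574). This restates the fall of the list's odds ratio to 1.45 at that IDR, so a property of the weaker peaks and a property of these genes cannot be told apart.

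The recurrent 8-mers were weighed against base composition. Summit windows on 3L, 3R and 4 were 63.5% A and T, against 56.2% in their flanks. The 8-mers of A and T alone were in 39.8% of windows, 2.21 times the higher flank share, which argues against regional composition. They were 1.37 times as frequent as in windows shuffled with their dinucleotides kept, above the highest of 20 shuffles (30.9%) but short of the bound of 1.5 set beforehand, so composition of the window itself and a specific sequence cannot be told apart. CACTGTG was 5.3 times as frequent as in shuffled windows (8.45% against a mean of 1.59%), which composition does not account for.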

How the results depend on the processing

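Alternatives set after the data were seen are an IDR of 0.001, the left-out peaks counted as passing, flanks for the 8-mers, and 3L, 3R and 4 alone for CACTGTG in left-out peaks (odds ratio 0.493 in place of 0.215). The promoter excess, the shorter TSS distance and the 3 depleted gene lists kept their direction and their side of the threshold in all settings run. Each setting ranked its own 10 8-mers, all of which passed, but only 5 were shared with the first search after exchange of the arms, 6 with windows of 50 bp and 6 without replicate 1. The mean number of peaks was 780 per replicate at an IDR of 0.001, and 1245 to 1433.5 without 1 replicate. The mean share of peaks between replicates was 65.3% with 50% overlap of both peaks, 68.9% with summits within 100 bp, and 70.1 to 71.4% for single pairs. The share of conservative peaks in all replicates fell to 28.8% with 50% overlap, and was 39.9 to 46.9% for pairs. Without 1 replicate, 0 to 1 arms passed in place of 3, 0 gene lists were higher in place of 2, 2 to 4 motifs were higher in place of 8, and 1 motif was lower in place of 2 each time. Higher gene lists numbered 0 at an IDR of 0.001 and 1 with left-out peaks, with summits within 200 bp, and with all annotated genes as background. Higher motifs numbered 4 at an IDR of 0.001 and 2 with windows of 50 bp. Lower motifs numbered 0 in the longest other list and 1 at an IDR of 0.001, with left-out peaks, with 50 bp and among promoter peaks. Odds ratios turned, with a Fisher adjusted p under 0.05 before or after, for arm X in the longest list (0.987), arm 4 against random positions (0.141) and other contigs with left-out peaks (1.66). They turned likewise for introns with a promoter of 200 bp (1.11), snoRNA genes at 200 bp (0.0783) and oxidative phosphorylation genes at 5 kb (2.05). The same held for GAGA at 50 bp (0.596) and Caudal among promoter peaks (1.37), though neither motif was called against both backgrounds before or after. The stricter sets hold fewer peaks, and otherwise the cause was not tested.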

Other observations

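The comparisons here were all chosen after the data were seen. At promoters the summits lay on the upstream side of the gene. Of 1038 peaks within 500 bp of a protein-coding TSS, 854 (82.3%) were upstream of it, against 39.2% of failed candidates (odds ratio 7.2, 95% interval 6.12 to 8.47), and the median summit was at -116 bp. The promoter share followed the signal: 67.7% of the 434 peaks of highest signal were at promoters, 55.1, 50.1 and 44% in the following groups of about that size and 36.6% in the lowest 435 (highest against lowest, Fisher's exact test, odds ratio 3.65, adjusted p = 9.98e-20). Of the highest 434, 98.4% were called in all 3 replicates.

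CACTGTG was found within 100 bp of 8.45% of summits on 3L, 3R and 4 against 2.69% of failed candidates (odds ratio 3.34, 95% interval 2.64 to 4.22). It was less frequent at promoter peaks (8.54%) than at other peaks (11.5%, Fisher adjusted p = 0.0351), and more frequent in the highest 434 by signal (12.7%) than in the lowest 435 (8.05%, adjusted p = 0.0351), without a steady fall between them (8.99, 9.89 and 10.4%). Of the 20 named genes only px had it at its peak. Genes of the mitochondrial ribosome other than the named mRpL41 and mRpL23 had peaks at 9 of 67 (13.4% against 12.9% of other genes, Fisher adjusted p = 0.855), so no excess was found in the group. Among those 9, mRpS23 had the peak also assigned to CenG1A (signal 1086) and mRpS10 the peak also assigned to Art3 (signal 1002). The values of p are adjusted over 8 comparisons.

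The 13.3 kb around CG2889 held 24 candidates with a median signal of 38.4, above 98.8% of 9121 windows of that width on X with at least 5 candidates, whose median was 23.2. The copy number of this locus, which the transgene can change, was not tested as a source of the higher signal.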
